A study of Homo sapiens with 12 samples.

How the data were processed

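The deposited files hold 1 count per gene and library, which the authors describe as reads counted without strand. Per the submitters' processing notes the tools were STAR, HTSeq and edgeR and the genome build hg19, with no versions or settings. Counts were used as given, and summary lines of the counting tool were left out. Of 57773 gene identifiers 90.59% were named, from a table of gene names and from GENCODE release 29. Mitochondrial genes had 0 counts in all libraries, so they could not be used to judge the libraries. Library totals were 12804408 to 23997055 counts. TMM factors lay between 0.889 and 1.084. The iNN WT library with DOX had the lowest total, the lowest TMM factor and the lowest share of counts on ribosomal protein genes (1.09%, against 1.63% to 4.41%). Across genes it correlated with the iAD libraries with DOX at 0.862 and 0.861, and the iNN KO library at 0.896 and 0.874.

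The model was chosen before the data were examined, from the labels alone, along with the gene lists, the fixed genes and most of the alternatives. edgeR 4.0.16 fitted 1 coefficient for each of the 6 states (line and DOX) and 1 for genotype to all 12 libraries, with TMM normalization, filterByExpr at a minimum count of 10, a quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. The replicate number of the labels is the genotype, so a library of a state has its partner in the other genotype, and genotype is in the model. This leaves 5 residual degrees of freedom (4 where the KO effect may differ with DOX), and the error is how far WT and KO libraries of a state differ beyond a shared genotype effect. The prior degrees of freedom were 3.79 and the common biological coefficient of variation 0.386. The filter removed 15699 genes, and log2 CPM used a prior count of 2. Interaction contrasts set the DOX response of a line against that of another. The KO comparisons used the same fit or 1 with a KO by DOX term.

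Gene lists were 36 in number with 481 symbols, written from general knowledge before the data were examined, and 17 of them are on glycosylation. They were tested with camera (limma 3.58.1) at its preset correlation of 0.01 between genes, again with a correlation estimated from the data, and with fry, each with Benjamini-Hochberg adjustment over the 36 lists of a comparison. Camera called 68 of 252 tests, fry 80, and camera with an estimated correlation 0, where the smallest adjusted p was 0.140. A list's genes are also adjusted over the list alone. Medians are given again with genes at 0 set to a floor of 3 counts per library.

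A fixed rule set which genes could be named, and the text gives only some of them. The lineage factors shown and the 7 fixed N-glycan genes are given in each comparison of states. In the interaction contrasts some of those not called are named without values. From each list described come up to 3 called genes with the largest change and a mean log2 CPM of at least 1, or up to 2 as values where none is called. From all genes come the 5 highest and 5 lowest called with a mean log2 CPM of at least 4 and a symbol that is not a clone, pseudogene or antisense name. Many of these highest and lowest genes are not named, and the choice among them followed no fixed rule. For DOX in iNN none of them is named. For the KO the rule asks for genes that move the same way in 6 states. As none was called, a selection from those with the smallest p is given as values. Genes named with values by state in the comparison without DOX are called ones. Near-identical gene copies and genes whose exons overlap another gene (such as MGAT2, TUBB3, GMPPB, GALNT4 and NDST2) have uncertain counts. Other list genes overlap too, among them ECSCR (72.5% of exonic bases), PRPH (56.2%) and NEFM (38.9%). Genes that could bear on the identity of the donor are not reported here.

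Versions were R 4.3.3, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. The pipeline was tested on simulated counts with the dispersions of the data, over 21817 genes of which 200 were changed, and results are given with the comparisons. The changed genes were drawn only from genes with higher counts and outside the most variable ones. Recovery of changes in genes with low counts or high variability was thus not measured. Each simulated gene had the same dispersion in all libraries, and in several comparisons of the data far more genes were called than were changed here. The rates of recovery and of unchanged calls therefore describe the simulated setting and not the comparisons themselves. Alternatives tried were DESeq2 size factors, no filter for low counts, a stricter filter (CPM of 1 in 2 libraries), DESeq2 in place of edgeR, no genotype term, the 6 libraries without DOX as 1 group, only the 4 libraries of a comparison, an additive model and each line left out for the KO, and each library left out in turn. Leaving out 1 library not in a comparison, and leaving out both iNN KO with DOX and iE KO without DOX, were chosen after seeing the data. No raw reads, mass spectrometry of glycans or record of the culture days were among the files.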

Results

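The files hold read counts per gene from polyA RNA of 12 cultures, all made from the published human induced pluripotent stem cell line PGP1. Per the labels, the cells are lentivirus-infected polyclonal populations of 3 lines with the code names iAD, iNN and iE, each wild type (WT) or knockout (KO), and each grown without doxycycline (DOX) or with 5 µM DOX. The labels do not spell out the code names, name no delivered factor, and do not name the gene that was knocked out, so the level of that gene cannot be reported. The questions are which genes of cell identity and of glycan synthesis change with DOX in each line, how the lines differ with DOX, and what the KO changes.

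Each combination of line, genotype and DOX is 1 library, so no state has replicates of 1 genotype, and the n = 2 libraries of a state are always 1 WT and 1 KO library. Libraries held 12804408 to 23997055 counted reads, and 21817 genes passed the filter for low counts. Levels are counts scaled to library size (CPM), given as mean ± SD of the n = 2 libraries of a state. Log2 fold changes (log2 FC) are given ± a standard error derived from the F test. It is the absolute log2 FC over the square root of F, so it restates the unadjusted p and is no separate measure of spread. Adjusted p values come from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over all genes unless another tool is named, and a gene is called where the value is under 0.05. Where a group has no reads at all, the fold is a bound that sets the group at 3 counts per library, and these bounds cover counting error only. WT and KO libraries of a state correlated across genes at r = 0.963 to 0.987 without DOX, at 0.976 in iAD with DOX and at 0.970 in iE with DOX. In iNN with DOX the value was 0.880, and 44.9% of genes lay over 2-fold apart between WT and KO, against 7.8% to 21.7% in the other states.

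Genes of the endothelium and of neurons differed between the lines with DOX, and pluripotency genes were high in all libraries without it. The median of 16 pluripotency genes was 6.32 to 6.96 log2 CPM in the 6 libraries without DOX, and that of 17 pan-neuronal genes was 3.75 to 4.37. With DOX the pan-neuronal median reached 7.88 and 7.98 in iAD, 9.79 and 8.71 in iNN (WT and KO), and was 2.75 and 3.30 in iE. The endothelial median was 6.98 and 7.85 in iE with DOX, -0.44 and -0.53 in iAD, and -1.13 and 1.70 in iNN. In the iNN KO library with DOX the pluripotency median stayed at 5.40, against 1.25 in its WT partner, and the proliferation median at 6.32 against 2.21.

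**Figure D1:**
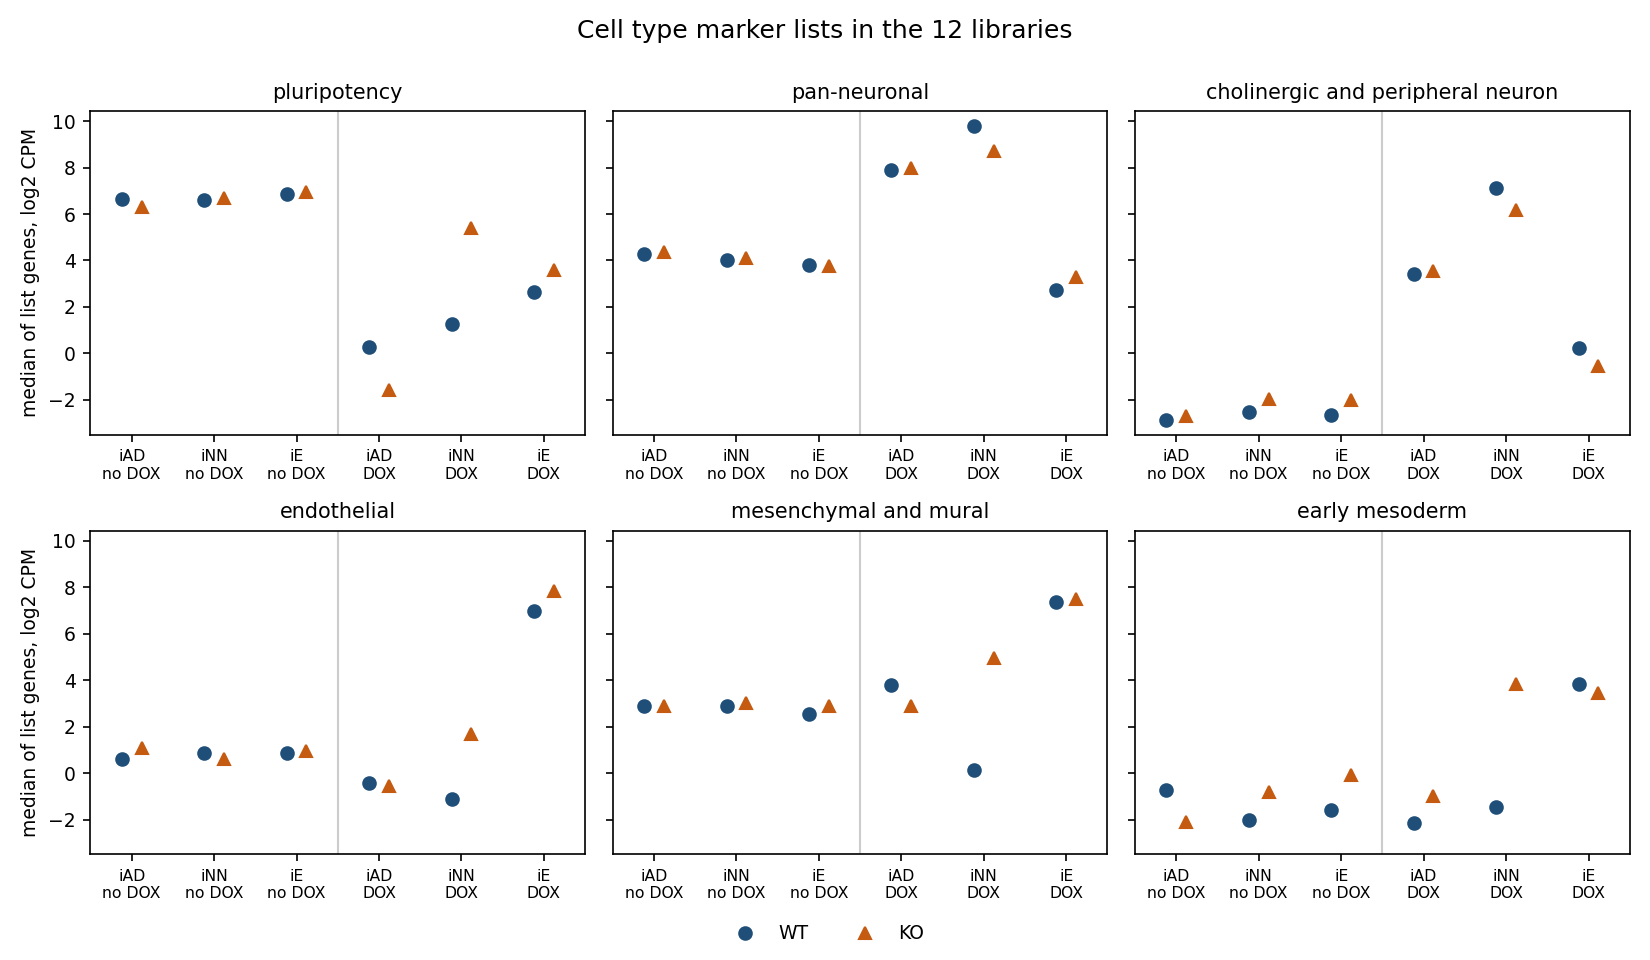
Median log2 CPM of 6 gene lists of cell identity in each of the 12 libraries, with WT as circles and KO as triangles.

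The lines were first compared without DOX, to ask whether they differ before induction. ETV2 (ENSG00000105672), a factor that directs mesoderm to endothelial and blood fate, stood at 169 and 36.0 CPM in the iE WT and KO libraries without DOX (3277 and 764 counts). It was at 0.838 to 1.84 CPM in the other lines. NLRP2, an innate immune gene, was at 92.3 and 49.8 CPM in iAD and at 3.39 to 4.13 CPM elsewhere. BPIFB4, of the lipid transfer family, was at 88.9 and 94.7 CPM in iNN against 0 to 0.247 CPM. ZNF528, a zinc finger gene, was low only in iAD (0.496 and 0.148 CPM, against 21 to 37.3 CPM). UBBP4, a ubiquitin gene copy whose reads are uncertain because near-identical copies exist, was at 26.4 and 44.7 CPM in iAD and at 0.764 to 4.19 CPM in the others. These genes were among the 6 called between lines, with 363 at unadjusted p under 0.05 and 52 called by DESeq2. The 6 became 1 without iAD WT, iE WT or iAD KO, 0 without iNN WT or iNN KO, 2 without iE KO (all without DOX), and 38 without iNN KO with DOX.

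DOX in the iAD line was tested next, to ask which genes change in these cells. DLX2 (ENSG00000115844), a factor of inhibitory neuron fate in the forebrain, rose from 0 counts to 40.1 ± 10.1 CPM (at least 223-fold higher, adjusted p = 0.00548). NEUROG1 (ENSG00000181965), a factor of excitatory and sensory neurons, rose from 0 counts to 6.98 ± 6.55 CPM (at least 38.7-fold higher, adjusted p = 0.00335), with 185 counts in WT and 44 in KO. NEUROG2 (ENSG00000178403), of the same family, was called as higher at 2.29 ± 1.73 against 0.0740 ± 0.105 CPM, adjusted p = 0.0150. ETV2 was not called (1.13 ± 0.0888 against 1.34 ± 0.710 CPM, log2 FC -0.17 ± 0.69, adjusted p = 0.879). Reads of these factors cannot separate a delivered copy from the endogenous gene. Leaving out iAD WT with DOX or iAD WT without DOX ended the call of NEUROG2.

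Most genes of the pan-neuronal list were higher and most of the pluripotency list lower in iAD with DOX. STMN2, a microtubule protein of growing axons, rose from 3.93 ± 1.16 to 1054 ± 24.4 CPM (log2 FC 8.06 ± 0.72, adjusted p = 3.82e-04). The neuronal RNA-binding ELAVL3 rose from 1.94 ± 0.0420 to 212 ± 2.36 CPM (log2 FC 6.78 ± 0.75, adjusted p = 7.85e-04). SNAP25 of the synaptic release machinery rose from 1.57 ± 0.423 to 168 ± 25.5 CPM (log2 FC 6.72 ± 0.70, adjusted p = 6.43e-04). NANOG, a core pluripotency factor, fell from 28.0 ± 2.32 CPM to 0 counts (at least 161-fold lower, adjusted p = 0.00335). ESRG, a long noncoding RNA of stem cells, fell from 849 ± 161 to 0.273 ± 0.235 CPM (log2 FC -11.57 ± 1.39, adjusted p = 0.00101). The neural progenitor factor SOX1 rose from 0 counts to 79.6 ± 21.3 CPM (at least 441-fold higher, adjusted p = 3.84e-04). The intermediate filament gene PRPH of peripheral neurons rose from 0 counts to 9.43 ± 0.633 CPM (at least 52.3-fold higher, adjusted p = 9.46e-04). DLX5, a forebrain factor downstream of DLX2, rose from 0 counts to 20.1 ± 2.55 CPM (at least 111-fold higher, adjusted p = 0.00129). The AMPA receptor gene GRIA2 rose from 0 counts to 86.1 ± 21.8 CPM (at least 477-fold higher, adjusted p = 0.00102). Of the highest calls, HEPACAM2, an adhesion gene, rose from 0 counts to 354 ± 123 CPM (at least 1970-fold higher, adjusted p = 2.63e-04). NR2F1, a nuclear receptor of the cortex, rose from 0 counts to 274 ± 59.8 CPM (at least 1520-fold higher, adjusted p = 0.00153). CLDN5, a tight junction gene of endothelium, rose from 0.526 ± 0.443 to 171 ± 5.82 CPM (log2 FC 8.41 ± 0.84, adjusted p = 5.72e-04). KDR, a receptor of the same list, fell from 225 ± 44.1 to 0.372 ± 0.451 CPM (log2 FC -9.26 ± 1.53, adjusted p = 0.00352). The endoderm factor FOXA2 was called as higher at 152 ± 58.8 against 0.0848 ± 0.0196 CPM, adjusted p = 3.35e-04.

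By list, pan-neuronal genes in iAD gave 14 of 17 genes higher, 1 lower and 2 not called (16 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.09e-07, and adjusted p = 0.424 with an estimated correlation). In the neural progenitor list 8 of 8 genes were higher, 0 lower and 0 not called (camera adjusted p = 1.65e-04, and adjusted p = 0.405 with an estimated correlation). Among cholinergic and peripheral neuron genes 8 of 10 genes were higher, 0 lower and 2 not called (camera adjusted p = 2.46e-06, and adjusted p = 0.294 with an estimated correlation). Among pluripotency genes 0 of 16 genes were higher, 12 lower and 4 not called (0 higher and 13 lower adjusted over the list alone, camera adjusted p = 6.39e-07, and adjusted p = 0.613 with an estimated correlation), with median log2 FC -6.30, or -5.73 with genes at 0 at their bound. The GABAergic list gave 7 of 14 genes higher, 1 lower and 6 not called (camera adjusted p = 0.0306, and adjusted p = 0.687 with an estimated correlation). Endothelial genes were split: 4 of 21 genes were higher, 8 lower and 9 not called (camera adjusted p = 0.131). Mesenchymal and mural genes had a median of -0.51 and a mean of 2.45, opposite in sign, with camera adjusted p = 0.617.

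The glycan genes called in iAD lie at several steps of the pathway. ST8SIA4, a polysialyltransferase, rose from 0.558 ± 0.188 to 32.1 ± 9.52 CPM (log2 FC 5.82 ± 0.74, adjusted p = 0.00131). ST8SIA2, its partner in the nervous system, rose from 3.81 ± 1.33 to 68.6 ± 17 CPM (log2 FC 4.20 ± 0.69, adjusted p = 0.00339). MGAT4A, which starts a GlcNAc branch, rose from 10.2 ± 0.668 to 65.1 ± 11.6 CPM (log2 FC 2.67 ± 0.30, adjusted p = 8.17e-04). The Golgi mannosidase MAN2A2 rose from 16.2 ± 0.891 to 88.9 ± 31.7 CPM (log2 FC 2.41 ± 0.38, adjusted p = 0.00301). FUT9 (ENSG00000172461), which makes the Lewis x epitope, rose from 14.2 ± 1.82 to 60.8 ± 4.04 CPM (log2 FC 2.13 ± 0.51, adjusted p = 0.0150). FUT8 (ENSG00000033170), which adds core fucose, rose from 33.0 ± 3.55 to 69.7 ± 3.83 CPM (log2 FC 1.08 ± 0.24, adjusted p = 0.0112). ST6GAL1 (ENSG00000073849), the enzyme of α2,6 sialic acid, fell from 157 ± 17.7 to 66.2 ± 4.90 CPM (log2 FC -1.25 ± 0.31, adjusted p = 0.0176). MGAT1 (ENSG00000131446), which opens the way to complex N-glycans, was not called (94.6 ± 4.54 against 107 ± 11.7 CPM, log2 FC -0.18 ± 0.31, adjusted p = 0.684). MGAT3 (ENSG00000128268), the bisecting enzyme, was not called (38.3 ± 8.63 against 23.0 ± 0.0345 CPM, log2 FC 0.72 ± 0.44, adjusted p = 0.243). Nor was MGAT5 (ENSG00000152127), a branching enzyme (103 ± 25.1 against 76.3 ± 17 CPM, log2 FC 0.48 ± 0.49, adjusted p = 0.486). ST3GAL4 (ENSG00000110080), an α2,3 sialyltransferase, was not called either (24.8 ± 0.923 against 24.6 ± 0.0990 CPM, log2 FC 0.01 ± 0.25, adjusted p = 0.988). Leaving out any of the 4 iAD libraries ended the calls of FUT8 (0.96 to 1.20) and ST6GAL1 (-1.45 to -1.04). The call of FUT9 (1.73 to 2.23) was lost without iAD KO with DOX, iAD KO without DOX or iAD WT without DOX.

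Among N-glycan sialyltransferases in iAD 4 of 8 genes were higher, 1 lower and 3 not called (camera adjusted p = 0.133). Among branching and bisection genes 3 of 8 genes were higher, 0 lower and 5 not called (camera adjusted p = 0.0838). Fucosyltransferases gave 3 of 8 genes higher, 0 lower and 5 not called (3 higher and 1 lower adjusted over the list alone). Golgi mannosidases gave 4 of 6 genes higher, 1 lower and 1 not called (5 higher and 1 lower adjusted over the list alone). Glycolipid synthesis had 5 of 9 genes higher, 0 lower and 4 not called, with the ganglioside enzyme ST3GAL5 among them (69.6 ± 1.16 against 6.75 ± 2.78 CPM, log2 FC 3.39 ± 0.54, adjusted p = 0.00295). In glycosaminoglycan synthesis 10 of 29 genes were higher, 2 lower and 17 not called (camera adjusted p = 0.0369, and adjusted p = 0.687 with an estimated correlation). NDST4, a heparan sulfate enzyme, rose from 0 counts to 23.9 ± 1.46 CPM (at least 133-fold higher, adjusted p = 0.00134). Nucleotide sugar synthesis had 3 of 23 genes higher, 7 lower and 13 not called (camera adjusted p = 0.176). GFPT2, the entry to the hexosamine pathway, fell from 249.6 ± 9.39 to 12.1 ± 0.450 CPM (log2 FC -4.35 ± 0.55, adjusted p = 0.00127). UGP2, which makes UDP-glucose, fell from 840.4 ± 48.8 to 126 ± 0.850 CPM (log2 FC -2.73 ± 0.45, adjusted p = 0.00347). In the lipid-linked precursor list 1 of 24 genes were higher, 6 lower and 17 not called (camera adjusted p = 0.284). Its first enzyme DPAGT1 fell from 68.4 ± 2.99 to 21.1 ± 2.35 CPM (log2 FC -1.70 ± 0.25, adjusted p = 0.00209).

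In all, 6519 genes were called in iAD, 3704 higher and 2815 lower. The direction was the same in WT and KO for 3704 and 2814 of them. The error of the test is the disagreement of WT and KO, so being called largely fixes this count. It is therefore no separate support. Over all genes the WT and KO responses correlated at r = 0.882. The count became 1906 without iAD WT without DOX, 2187 without iAD KO without DOX, 3179 without iAD WT with DOX and 2044 without iAD KO with DOX. It became 10517 without iNN KO with DOX, which is not part of the comparison but enters the error.

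DOX in the iNN line was tested with the same question. NEUROG1 and NEUROG2 drive cells to excitatory neurons. NEUROG2 rose from 0 counts to 50.2 ± 6.58 CPM (at least 357-fold higher, adjusted p = 0.00102). NEUROG1 was called as higher at 83.1 ± 21.8 against 0.0700 ± 0.0314 CPM, adjusted p = 9.79e-04. DLX2 (0.807 ± 1.14 against 0.188 ± 0.00464 CPM, adjusted p = 0.272) and ETV2 (1.66 ± 0.735 against 0.964 ± 0.123 CPM, log2 FC 0.91 ± 0.68, adjusted p = 0.328) were not called. STMN2 rose from 4.83 ± 0.0530 to 3893 ± 1702 CPM (log2 FC 9.67 ± 0.77, adjusted p = 2.81e-04). ELAVL3 rose from 1.69 ± 0.224 to 446 ± 105 CPM (log2 FC 8.09 ± 0.79, adjusted p = 4.53e-04). Its relative ELAVL4 rose from 2.63 ± 0.463 to 692 ± 275 CPM (log2 FC 8.03 ± 0.48, adjusted p = 9.97e-05). CHAT, the enzyme of acetylcholine, rose from 0 counts to 51.9 ± 35.0 CPM (at least 368-fold higher, adjusted p = 0.00207). The vesicular glutamate transporter gene SLC17A6 rose from 0.233 ± 0.127 to 219 ± 48.3 CPM (log2 FC 9.84 ± 0.76, adjusted p = 2.71e-04). The stem cell DNA methyltransferase DNMT3B fell from 3917 ± 76.0 to 84.3 ± 91.9 CPM (log2 FC -5.62 ± 0.88, adjusted p = 0.00264). The replication gene MCM5 fell from 448 ± 0.872 to 42.1 ± 42.0 CPM (log2 FC -3.44 ± 0.72, adjusted p = 0.00871). 

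Every gene of the cholinergic and peripheral neuron list was called in iNN. There 10 of 10 genes were higher, 0 lower and 0 not called (camera adjusted p = 9.81e-09, and adjusted p = 0.140 with an estimated correlation; median log2 FC 9.57, or 9.05 with genes at 0 at their bound). Of pan-neuronal genes 16 of 17 genes were higher, 0 lower and 1 not called (camera adjusted p = 4.56e-10, and adjusted p = 0.499 with an estimated correlation). Of glutamatergic genes 7 of 11 genes were higher, 1 lower and 3 not called (camera adjusted p = 0.0210, and adjusted p = 0.499 with an estimated correlation). Pluripotency genes gave 0 of 16 genes higher, 7 lower and 9 not called (camera adjusted p = 2.29e-04, and adjusted p = 0.805 with an estimated correlation). Proliferation genes gave 0 of 20 genes higher, 6 lower and 14 not called (camera adjusted p = 7.33e-05, and adjusted p = 0.805 with an estimated correlation). These last lists moved with the KO library with DOX, in which the medians of KO minus WT were 4.24 and 4.43 on the log2 scale. In the same library endothelial genes stood 3.65, mesenchymal genes 4.03 and early mesoderm genes 5.66 above WT at the median, and pan-neuronal genes were at -1.32. For endothelial genes 2 of 21 genes were higher, 4 lower and 15 not called (1 higher and 3 lower adjusted over the list alone), with a median of -0.06 and a mean of 0.09. Glial genes (median -0.28, mean 0.19) and mesenchymal genes (median -0.18, mean 2.04) also differed in sign between the 2 measures.

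Of the sialyltransferases in iNN, 5 rose. ST8SIA4 rose from 0.492 ± 0.0874 to 13.2 ± 4.42 CPM (log2 FC 4.74 ± 0.71, adjusted p = 0.00222). ST8SIA2 rose from 4.97 ± 1.62 to 122 ± 122 CPM (log2 FC 4.41 ± 0.69, adjusted p = 0.00265). ST3GAL6, an α2,3 sialyltransferase, rose from 3.86 ± 0.933 to 40.2 ± 16.6 CPM (log2 FC 3.35 ± 0.33, adjusted p = 4.53e-04). MGAT4A rose from 8.48 ± 1.12 to 115 ± 9.77 CPM (log2 FC 3.77 ± 0.31, adjusted p = 3.08e-04). MGAT5B, a branching enzyme of the brain, rose from 11.7 ± 0.0420 to 76.4 ± 46.3 CPM (log2 FC 2.64 ± 0.44, adjusted p = 0.00332). MGAT3 rose from 25.2 ± 0.438 to 115 ± 79.8 CPM (log2 FC 2.14 ± 0.46, adjusted p = 0.00955). FUT8 rose from 31.4 ± 1.25 to 84.8 ± 2.29 CPM (log2 FC 1.43 ± 0.24, adjusted p = 0.00332). B3GAT2, which makes the HNK-1 epitope of neural cells, rose from 2.39 ± 0.273 to 88.4 ± 70.6 CPM (log2 FC 5.18 ± 0.75, adjusted p = 0.00187). CHST8, which puts sulfate on terminal GalNAc, rose from 21.1 ± 1.04 to 130.1 ± 14.1 CPM (log2 FC 2.62 ± 0.27, adjusted p = 5.44e-04). The ganglioside enzyme ST8SIA1 rose from 2.79 ± 0.562 to 164 ± 63.8 CPM (log2 FC 5.88 ± 0.52, adjusted p = 3.45e-04). MGAT1 (66.9 ± 17.6 against 109.7 ± 2.61 CPM, log2 FC -0.71 ± 0.31, adjusted p = 0.109) and MGAT5 (238 ± 144 against 84.6 ± 2.39 CPM, log2 FC 1.43 ± 0.50, adjusted p = 0.0586) were not called. FUT9 was not called either (8.20 ± 6.69 against 11.9 ± 0.667 CPM, log2 FC -0.68 ± 0.50, adjusted p = 0.324). ST6GAL1 (183 ± 41.0 against 144 ± 1.45 CPM, log2 FC 0.34 ± 0.30, adjusted p = 0.421) and ST3GAL4 (15.9 ± 0.826 against 23.1 ± 0.106 CPM, log2 FC -0.54 ± 0.25, adjusted p = 0.131) were not called. Leaving out iNN KO without DOX or iNN WT without DOX ended the call of MGAT3 (1.97 to 2.26). The calls of MGAT5B (2.43) and FUT8 (1.35) were lost without iNN WT without DOX.

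The sialyltransferase list in iNN had 5 of 8 genes higher, 0 lower and 3 not called (camera adjusted p = 0.0338, and adjusted p = 0.499 with an estimated correlation). Branching and bisection had 3 of 8 genes higher, 0 lower and 5 not called (4 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.256). Other terminal modification had 4 of 7 genes higher, 2 lower and 1 not called. Glycolipid synthesis had 6 of 9 genes higher, 3 lower and 0 not called. Nucleotide sugar synthesis had 3 of 23 genes higher, 8 lower and 12 not called (camera adjusted p = 0.237). GFPT2 fell from 172 ± 13 to 23.6 ± 21.7 CPM (log2 FC -3.06 ± 0.53, adjusted p = 0.00388). GMDS, of GDP-fucose synthesis, fell from 67.1 ± 5.14 to 14.4 ± 1.74 CPM (log2 FC -2.22 ± 0.32, adjusted p = 0.00181). In glycan catabolism 0 of 13 genes were higher, 5 lower and 8 not called (2 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.286). The fucosidase FUCA2 fell from 55.1 ± 0.297 to 17.2 ± 2.56 CPM (log2 FC -1.68 ± 0.28, adjusted p = 0.00309). O-GalNAc genes had 7 of 30 genes higher, 4 lower and 19 not called, with a median of -0.12 and a mean of 0.30. GALNT3 fell from 28.2 ± 1.03 to 1.38 ± 1.33 CPM (log2 FC -4.46 ± 0.69, adjusted p = 0.00256).

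In iNN 6844 genes were called, 3981 higher and 2863 lower. Of these 3966 and 2863 had the same direction in WT and KO, which the test largely fixes, as in iAD. The responses correlated at r = 0.696 over all genes. With only the 4 libraries of the comparison 593 genes were called, and 75 of 106 values of named genes lost their call. The count became 1956 without iNN WT without DOX, 2333 without iNN KO without DOX and 10831 without iNN KO with DOX. On simulated counts over 21817 genes with 200 changed, edgeR recovered 0%, 31% and 72.1% of genes changed 2-fold, 4-fold and 8-fold, and DESeq2 9.9%, 65.5% and 93.4%. Of the 68 genes called by edgeR and 160 by DESeq2, 6 and 57 were unchanged.

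DOX in the iE line was tested with the same question. ETV2, already present without DOX, was not called (38.7 ± 0.691 against 102 ± 94.1 CPM, log2 FC -1.23 ± 0.61, adjusted p = 0.195). EMCN, a sialomucin of the endothelial surface, rose from 0 counts to 97.5 ± 38.2 CPM (at least 659-fold higher, adjusted p = 0.00223). ESAM, an endothelial adhesion gene, was called as higher at 223 ± 68.4 against 0.0729 ± 0.0302 CPM, adjusted p = 1.98e-04. COL3A1, a fibrillar collagen of mesenchyme, rose from 1.31 ± 1.27 to 4430 ± 997 CPM (log2 FC 11.94 ± 1.94, adjusted p = 0.00517). The lymphoid GTPase GIMAP5 rose from 0 counts to 97.5 ± 2.89 CPM (at least 659-fold higher, adjusted p = 0.00291). The hepatic factor HNF4A rose from 0 counts to 17.6 ± 10.3 CPM (at least 119-fold higher, adjusted p = 9.60e-04). The germline and stem cell factor PRDM14 fell from 139 ± 62.4 to 0.770 ± 0.441 CPM (log2 FC -7.30 ± 1.18, adjusted p = 0.00500). DLX2 rose from 0 counts to 11.4 ± 6.54 CPM (at least 76.7-fold higher, adjusted p = 0.0129), at 399 counts in WT and 103 in KO. NEUROG2 was called from 0 counts without DOX and 15 and 6 with it, while NEUROG1 (6 and 0 counts with DOX) was not called. Leaving out any of the 4 iE libraries ended the call of NEUROG2. The call of DLX2 was lost without iE KO without DOX, iE WT with DOX or iE WT without DOX. Leaving out iE WT without DOX ended the call of COL3A1 (11.30).

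In the endothelial list 17 of 21 genes were higher, 0 lower and 4 not called (camera adjusted p = 2.14e-12, and adjusted p = 0.590 with an estimated correlation), with median log2 FC 6.41. Hematopoietic genes gave 5 of 10 genes higher, 0 lower and 5 not called (6 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.00327, and adjusted p = 0.590 with an estimated correlation). They stood 1.61 on the log2 scale higher in KO than in WT at the median with DOX. Mesenchymal and mural genes gave 6 of 12 genes higher, 0 lower and 6 not called (8 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.00133, and adjusted p = 0.748 with an estimated correlation). Endoderm genes gave 5 of 7 genes higher, 0 lower and 2 not called (camera adjusted p = 2.35e-04, and adjusted p = 0.590 with an estimated correlation). Interferon response genes gave 4 of 12 genes higher, 0 lower and 8 not called (camera adjusted p = 0.00299, and adjusted p = 0.652 with an estimated correlation). IFI6 of this list rose from 2.92 ± 0.475 to 44.4 ± 31.1 CPM (log2 FC 3.76 ± 0.57, adjusted p = 0.00379). In the pan-neuronal list 4 of 17 genes were higher, 4 lower and 9 not called. STMN2 rose from 4.65 ± 3.29 to 79.4 ± 33.7 CPM (log2 FC 4.10 ± 0.60, adjusted p = 0.00344). INA, a neurofilament gene, fell from 39.9 ± 1.88 to 3.52 ± 0.106 CPM (log2 FC -3.51 ± 0.52, adjusted p = 0.00346). Pluripotency genes gave 0 of 16 genes higher, 7 lower and 9 not called (0 higher and 11 lower adjusted over the list alone; camera adjusted p = 8.48e-05, and adjusted p = 0.724 with an estimated correlation). Of the metallothioneins 0 of 6 genes were higher, 5 lower and 1 not called (camera adjusted p = 4.80e-04, and adjusted p = 0.590 with an estimated correlation). Their level without DOX came from the KO library, whose list median was 6.51 log2 CPM against 1.96 in WT, and near-identical copies make single members uncertain.

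The glycan genes called in iE belong to several pathways. CSGALNACT1, which starts chondroitin sulfate, rose from 0.528 ± 0.347 to 33.0 ± 14.5 CPM (log2 FC 5.94 ± 0.70, adjusted p = 0.00140). CHSY3, which extends it, rose from 1.20 ± 0.167 to 22.4 ± 9.01 CPM (log2 FC 4.20 ± 0.63, adjusted p = 0.00372). The Golgi mannosidase MAN1A1 rose from 6.94 ± 1.56 to 175 ± 49.0 CPM (log2 FC 4.58 ± 0.56, adjusted p = 0.00160). MGAT1 rose from 85.9 ± 30.4 to 199 ± 27.8 CPM (log2 FC 1.21 ± 0.31, adjusted p = 0.0286). ST3GAL4 rose from 20.5 ± 3.65 to 41.8 ± 0.196 CPM (log2 FC 1.03 ± 0.25, adjusted p = 0.0242). FUT8 rose from 25.1 ± 2.96 to 45.9 ± 6.70 CPM (log2 FC 0.87 ± 0.24, adjusted p = 0.0351). FUT9 fell from 10.8 ± 4.07 to 1.36 ± 0.110 CPM (log2 FC -2.94 ± 0.55, adjusted p = 0.00839). CHST8 fell from 13.8 ± 3.42 to 0.793 ± 0.0119 CPM (log2 FC -4.11 ± 0.31, adjusted p = 3.83e-04). ST8SIA4 was called as higher at 31.9 ± 19.4 against 0.0516 ± 0.0729 CPM, adjusted p = 8.37e-04. MGAT3 was not called (35.0 ± 3.50 against 30.9 ± 7.67 CPM, log2 FC 0.17 ± 0.44, adjusted p = 0.826). Nor were MGAT5 (90.6 ± 33.0 against 61.4 ± 33.0 CPM, log2 FC 0.65 ± 0.50, adjusted p = 0.410) and ST6GAL1 (112 ± 42.6 against 129 ± 18.8 CPM, log2 FC -0.22 ± 0.30, adjusted p = 0.674). Leaving out any of the 4 iE libraries ended the calls of ST3GAL4 (0.85 to 1.22) and FUT8 (0.62 to 1.04). The call of MGAT1 (0.81 to 1.37) was lost without iE KO with DOX, iE KO without DOX or iE WT with DOX. Leaving out iE WT with DOX or iE WT without DOX ended the call of FUT9 (-2.70 to -2.62).

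Glycosaminoglycan synthesis in iE had 10 of 29 genes higher, 0 lower and 19 not called (13 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.35e-04, and adjusted p = 0.590 with an estimated correlation). Golgi mannosidases had 3 of 6 genes higher, 0 lower and 3 not called (camera adjusted p = 0.0483, and adjusted p = 0.600 with an estimated correlation). Other terminal modification had 0 of 7 genes higher, 2 lower and 5 not called (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0675). Sialyltransferases had 4 of 8 genes higher, 1 lower and 3 not called (camera adjusted p = 0.0615). O-GalNAc genes had 10 of 30 genes higher, 5 lower and 15 not called (12 higher and 6 lower adjusted over the list alone). Glycolipid synthesis, with 3 of 9 genes higher, 3 lower and 3 not called, had a median of 0.56 and a mean of -0.19. In iE 4088 genes were called, 2333 higher and 1755 lower. All had the same direction in WT and KO, which the test largely fixes, as in iAD. The responses correlated at r = 0.794 over all genes. The count became 1539 without iE WT without DOX, 1465 without iE KO without DOX, 1273 without iE WT with DOX, 1378 without iE KO with DOX and 7780 without iNN KO with DOX.

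**Figure D2:**
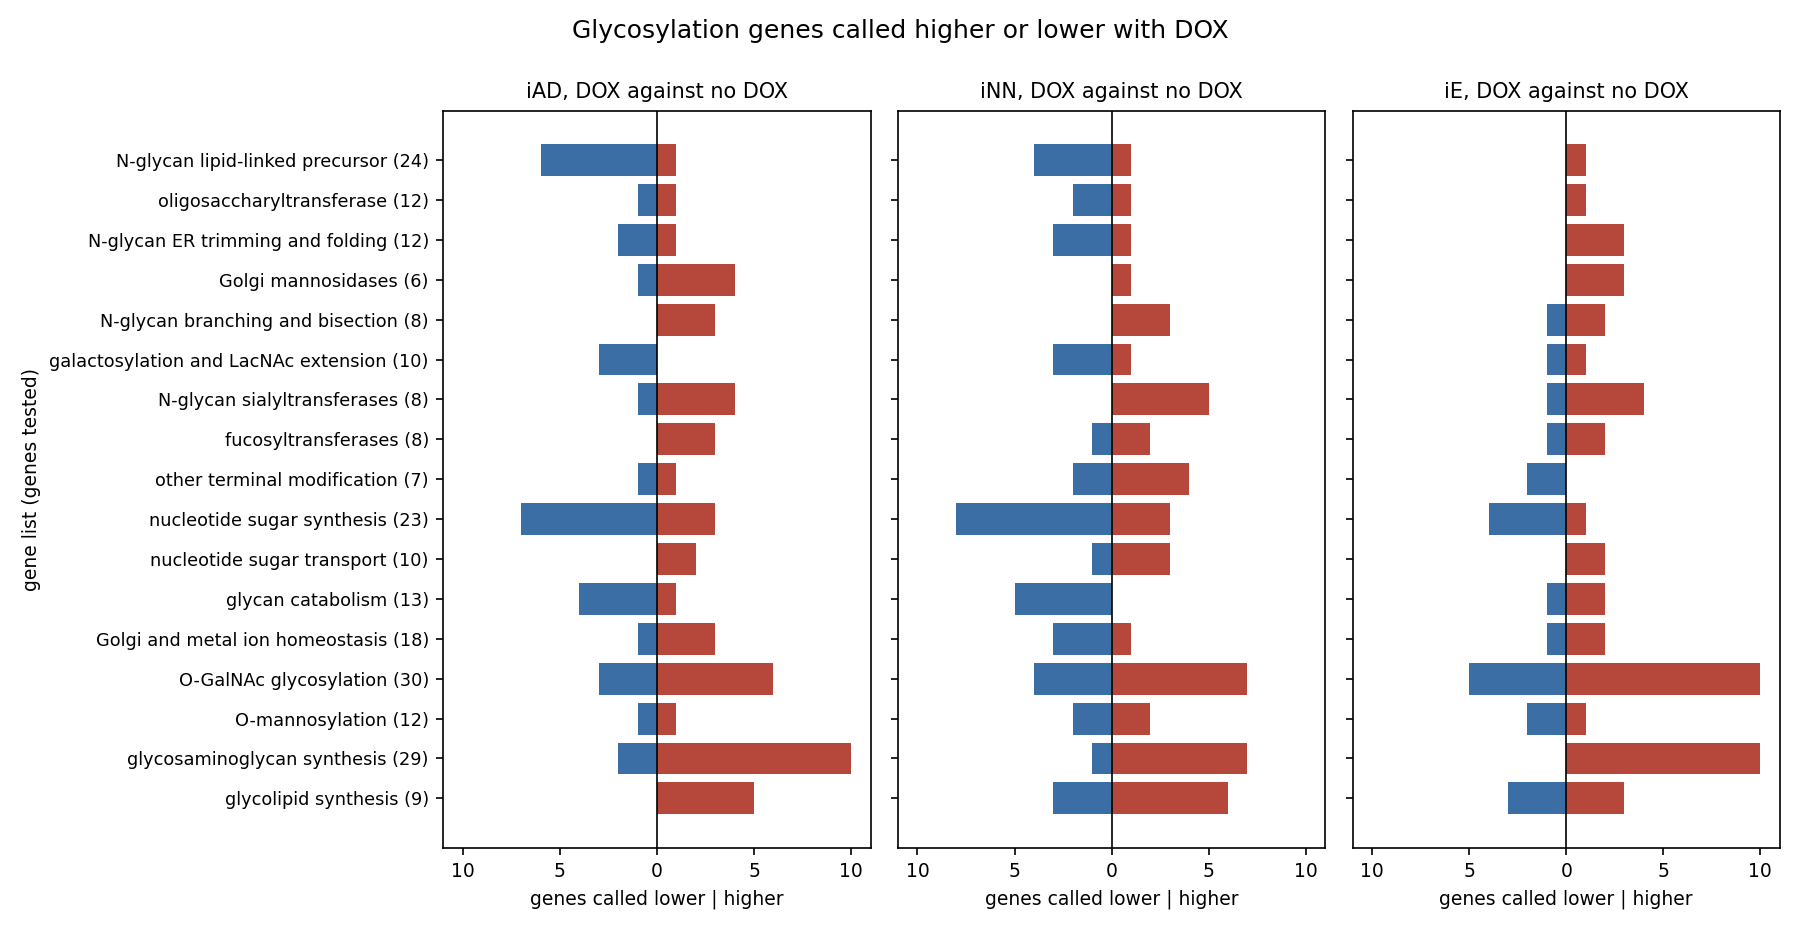
Number of genes called lower and higher with DOX in each of 17 glycosylation gene lists, for the 3 lines.

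The lists of called genes overlapped between lines. Higher genes of iAD and iNN shared 2451, against 676 expected if independent, and lower genes shared 1600 against 369. The calls are not independent, since all lines share the same fit and the same estimate of spread for a gene. Genes with high counts or little spread are easier to call in every line. An excess over the expected number can arise from this, so it does not measure shared biology. NDRG1, a gene of differentiation and hypoxia, is a shared higher call of all 3 lines. Its log2 FC was 3.08 ± 0.28, adjusted p = 3.82e-04, in iAD, 3.91 ± 0.28, adjusted p = 2.29e-04, in iNN and 2.75 ± 0.27, adjusted p = 7.44e-04, in iE. CDKN1A, a cell cycle inhibitor, is another (5.29 ± 0.57, adjusted p = 7.28e-04 in iAD; 4.15 ± 0.57, adjusted p = 0.00155 in iNN; 4.64 ± 0.57, adjusted p = 0.00161 in iE). UGP2 is a shared lower call (-2.73 ± 0.45, adjusted p = 0.00347 in iAD; -2.41 ± 0.45, adjusted p = 0.00533 in iNN; -3.06 ± 0.46, adjusted p = 0.00364 in iE). iAD and iE shared 1215 higher (396 expected) and 879 lower genes (226 expected), and iNN and iE 1160 (426 expected) and 855 (230 expected).

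iNN was then compared with iE, both with DOX, to ask how these lines differ. NEUROG2 was higher in iNN (50.2 ± 6.58 against 0.497 ± 0.148 CPM, log2 FC 6.67 ± 0.83, adjusted p = 0.00283). ETV2 was lower (1.66 ± 0.735 against 38.7 ± 0.691 CPM, log2 FC -4.44 ± 0.69, adjusted p = 0.00330). NEUROG1 was called as higher at 83.1 ± 21.8 against 0.12 ± 0.170 CPM, adjusted p = 0.00129. DLX2 was not called (0.807 ± 1.14 against 11.4 ± 6.54 CPM, log2 FC -3.92 ± 1.19, adjusted p = 0.0612). ELAVL3 (446 ± 105 against 0.396 ± 0.00595 CPM, log2 FC 10.13 ± 0.88, adjusted p = 2.97e-04) and INA (1994 ± 1575 against 3.52 ± 0.106 CPM, log2 FC 9.07 ± 0.66, adjusted p = 1.54e-04) were higher. DCX, a microtubule gene of migrating neurons, was higher as well (1093 ± 786 against 6.53 ± 2.49 CPM, log2 FC 7.33 ± 0.65, adjusted p = 3.27e-04). PLVAP, a gene of endothelial fenestrae, was lower (5.13 ± 7.25 against 887 ± 196 CPM, log2 FC -8.07 ± 1.37, adjusted p = 0.00490). So was the contractile actin gene ACTA2 (1.38 ± 1.20 against 72.8 ± 24.9 CPM, log2 FC -5.74 ± 0.80, adjusted p = 0.00291). HBE1, an embryonic globin gene, was lower too (0.261 ± 0.369 against 482 ± 629 CPM, log2 FC -10.71 ± 0.59, adjusted p = 1.38e-04). In iE with DOX its KO library lay 4.61 above WT on the log2 scale, so its level there is mainly that of 1 library. The genotype term of HBE1 (4.365) takes up most of this gap, so its p does not measure that spread. ONECUT3, a neuronal factor, was the highest call (461 ± 419 CPM against 0 counts, at least 2920-fold higher, adjusted p = 3.82e-04).

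Every tested pan-neuronal and endothelial gene was called between iNN and iE. In the pan-neuronal list 17 of 17 genes were higher, 0 lower and 0 not called (camera adjusted p = 1.03e-15, and adjusted p = 0.261 with an estimated correlation). In the cholinergic and peripheral list 10 of 10 genes were higher, 0 lower and 0 not called (camera adjusted p = 2.49e-08, and adjusted p = 0.162 with an estimated correlation). In the endothelial list 0 of 21 genes were higher, 21 lower and 0 not called (camera adjusted p = 2.00e-14, and adjusted p = 0.261 with an estimated correlation). Hematopoietic genes gave 0 of 10 genes higher, 6 lower and 4 not called (0 higher and 10 lower adjusted over the list alone; camera adjusted p = 4.11e-05, and adjusted p = 0.349 with an estimated correlation). Interferon response genes gave 0 of 12 genes higher, 6 lower and 6 not called (camera adjusted p = 3.30e-04, and adjusted p = 0.452 with an estimated correlation). Proliferation genes had 0 of 20 genes higher, 0 lower and 20 not called, with median log2 FC -1.50 and camera adjusted p = 0.00129, and adjusted p = 0.671 with an estimated correlation. Their medians were 2.21 log2 CPM in iNN WT and 6.32 in iNN KO, against 7.14 and 6.99 in iE.

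Glycan genes differed between iNN and iE at several steps. CHST8 (130.1 ± 14.1 against 0.793 ± 0.0119 CPM, log2 FC 7.34 ± 0.35, adjusted p = 5.78e-05) and B3GAT2 (88.4 ± 70.6 against 1.23 ± 0.944 CPM, log2 FC 6.18 ± 0.80, adjusted p = 0.00147) were higher. ST8SIA3, an α2,8 sialyltransferase of brain, was also higher (105 ± 84.9 against 2.66 ± 1.60 CPM, log2 FC 5.29 ± 0.72, adjusted p = 0.00184). MGAT5B (76.4 ± 46.3 against 5.35 ± 1.28 CPM, log2 FC 3.79 ± 0.46, adjusted p = 0.00116) and MGAT3 (115 ± 79.8 against 35.0 ± 3.50 CPM, log2 FC 1.66 ± 0.45, adjusted p = 0.0337) were higher. FUT9 (8.20 ± 6.69 against 1.36 ± 0.110 CPM, log2 FC 2.47 ± 0.55, adjusted p = 0.0152) and FUT8 (84.8 ± 2.29 against 45.9 ± 6.70 CPM, log2 FC 0.88 ± 0.24, adjusted p = 0.0307) were higher too. MGAT1 (66.9 ± 17.6 against 199 ± 27.8 CPM, log2 FC -1.57 ± 0.31, adjusted p = 0.00980) and ST3GAL4 (15.9 ± 0.826 against 41.8 ± 0.196 CPM, log2 FC -1.39 ± 0.25, adjusted p = 0.00666) were lower. B4GALT1, the main galactosyltransferase of N-glycans, was lower (16.0 ± 14.2 against 129.7 ± 62.6 CPM, log2 FC -3.08 ± 0.56, adjusted p = 0.00676). CSGALNACT1 was lower as well (0.854 ± 0.337 against 33.0 ± 14.5 CPM, log2 FC -5.23 ± 0.67, adjusted p = 0.00138). MGAT5 (238 ± 144 against 90.6 ± 33.0 CPM, log2 FC 1.29 ± 0.51, adjusted p = 0.106) and ST6GAL1 (183 ± 41.0 against 112 ± 42.6 CPM, log2 FC 0.71 ± 0.30, adjusted p = 0.135) were not called. Leaving out iE KO with DOX, iE WT with DOX or iNN WT with DOX ended the call of MGAT3 (0.70 to 1.89). The calls of FUT9 (2.07 to 2.78) and FUT8 (0.66 to 1.08) were lost without iE KO with DOX or iE WT with DOX. Leaving out iE KO with DOX ended the calls of MGAT1 (-1.38), ST3GAL4 (-1.36) and B4GALT1 (-2.71).

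Oligosaccharyltransferase genes had 0 of 12 genes higher, 4 lower and 8 not called between iNN and iE (camera adjusted p = 0.0397, and adjusted p = 0.657 with an estimated correlation). Endoplasmic reticulum trimming and folding had 0 of 12 genes higher, 5 lower and 7 not called (0 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.0268, and adjusted p = 0.538 with an estimated correlation). In branching and bisection 4 of 8 genes were higher, 1 lower and 3 not called (camera adjusted p = 0.147). In glycosaminoglycan synthesis 3 of 29 genes were higher, 10 lower and 16 not called (camera adjusted p = 0.0199, and adjusted p = 0.538 with an estimated correlation). In glycan catabolism 0 of 13 genes were higher, 6 lower and 7 not called (camera adjusted p = 0.0534). In all 4395 genes were called, 2461 higher in iNN and 1934 lower. With only the 4 libraries of the comparison 0 were called, and 95 of 100 values of named genes lost their call. The count became 9478 without iNN KO with DOX, 1626 without iE WT with DOX and 1594 without iE KO with DOX.

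iAD was compared with iE in the same way. ETV2 was lower in iAD (1.13 ± 0.0888 against 38.7 ± 0.691 CPM, log2 FC -5.11 ± 0.72, adjusted p = 0.00230). NEUROG1 was called as higher at 6.98 ± 6.55 against 0.12 ± 0.170 CPM, adjusted p = 0.00683. DLX2 (40.1 ± 10.1 against 11.4 ± 6.54 CPM, log2 FC 1.69 ± 1.01, adjusted p = 0.285) and NEUROG2 (2.29 ± 1.73 against 0.497 ± 0.148 CPM, log2 FC 2.10 ± 0.74, adjusted p = 0.0954) were not called. SOX1 (79.6 ± 21.3 against 1.02 ± 0.426 CPM, log2 FC 6.31 ± 0.65, adjusted p = 0.00102) and ELAVL3 (212 ± 2.36 against 0.396 ± 0.00595 CPM, log2 FC 9.02 ± 0.85, adjusted p = 5.37e-04) were higher. TH, the enzyme of dopamine synthesis, was higher too (17.5 ± 5.76 against 0.278 ± 0.116 CPM, log2 FC 6.02 ± 0.78, adjusted p = 0.00169). CD34, a surface gene of endothelium and blood stem cells, was lower (0 counts against 193 ± 94.0 CPM, at least 1110-fold lower, adjusted p = 0.00343). So was the fetal globin gene HBG2 (0 counts against 232 ± 299.7 CPM, at least 1330-fold lower, adjusted p = 0.00164), whose reads cannot be told from those of HBG1 with certainty. The HBG2 difference was -7.595 between the WT libraries and -12.025 between the KO libraries on the log2 scale. Its iE level is thus mainly that of the KO library, a spread that its p may not measure. In the pan-neuronal list 15 of 17 genes were higher, 0 lower and 2 not called (camera adjusted p = 1.99e-13, and adjusted p = 0.262 with an estimated correlation). In the neural progenitor list 7 of 8 genes were higher, 0 lower and 1 not called (camera adjusted p = 6.28e-05, and adjusted p = 0.262 with an estimated correlation). In the endothelial list 0 of 21 genes were higher, 19 lower and 2 not called (camera adjusted p = 9.84e-15, and adjusted p = 0.262 with an estimated correlation). Hypoxia and glycolysis genes had 0 of 12 genes higher, 4 lower and 8 not called (camera adjusted p = 0.0282, and adjusted p = 0.534 with an estimated correlation).

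Of the glycan genes, FUT9 was higher in iAD than in iE (60.8 ± 4.04 against 1.36 ± 0.110 CPM, log2 FC 5.5 ± 0.60, adjusted p = 8.34e-04). CHST8 (61.7 ± 6.84 against 0.793 ± 0.0119 CPM, log2 FC 6.27 ± 0.34, adjusted p = 1.31e-04) and ST8SIA3 (119.6 ± 32.2 against 2.66 ± 1.60 CPM, log2 FC 5.51 ± 0.72, adjusted p = 0.00172) were higher. MGAT4C, a relative of MGAT4A, was higher as well (32.2 ± 7.28 against 2.77 ± 0.0613 CPM, log2 FC 3.54 ± 0.46, adjusted p = 0.00171). MGAT1 (94.6 ± 4.54 against 199 ± 27.8 CPM, log2 FC -1.07 ± 0.31, adjusted p = 0.0420) and B4GALT1 (13.5 ± 2.25 against 129.7 ± 62.6 CPM, log2 FC -3.21 ± 0.57, adjusted p = 0.00604) were lower. The galactosidase GLB1 (53.5 ± 7.30 against 145 ± 36.2 CPM, log2 FC -1.43 ± 0.22, adjusted p = 0.00346) and CSGALNACT1 (1.12 ± 0.373 against 33.0 ± 14.5 CPM, log2 FC -4.87 ± 0.66, adjusted p = 0.00190) were lower. MGAT3 (0.11 ± 0.44, adjusted p = 0.893) and MGAT5 (0.17 ± 0.49, adjusted p = 0.837) were not called. FUT8 (0.60 ± 0.23, adjusted p = 0.106), ST6GAL1 (-0.74 ± 0.31, adjusted p = 0.122) and ST3GAL4 (-0.75 ± 0.25, adjusted p = 0.0662) were not called. In the oligosaccharyltransferase list 0 of 12 genes were higher, 0 lower and 12 not called (0 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.0345, and adjusted p = 0.534 with an estimated correlation). In trimming and folding 0 of 12 genes were higher, 4 lower and 8 not called (camera adjusted p = 0.0564). Leaving out iAD KO with DOX, iAD WT with DOX, iE KO with DOX or iE WT with DOX ended the call of MGAT1 (-1.28 to -0.89). The call of B4GALT1 (-3.11) was lost without iAD KO with DOX. In all 4205 genes were called, 2270 higher in iAD and 1935 lower. The count became 2141 without iAD WT with DOX, 1169 without iAD KO with DOX, 1500 without iE WT with DOX, 1587 without iE KO with DOX and 8507 without iNN KO with DOX.

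iAD was compared with iNN, both with DOX, to ask which genes part these lines. DLX2 was higher in iAD (40.1 ± 10.1 against 0.807 ± 1.14 CPM, log2 FC 5.62 ± 1.21, adjusted p = 0.0434). NEUROG1 (6.98 ± 6.55 against 83.1 ± 21.8 CPM, log2 FC -3.92 ± 0.69, adjusted p = 0.0241) and NEUROG2 (2.29 ± 1.73 against 50.2 ± 6.58 CPM, log2 FC -4.58 ± 0.74, adjusted p = 0.0187) were lower. ETV2 was not called (1.13 ± 0.0888 against 1.66 ± 0.735 CPM, log2 FC -0.67 ± 0.68, adjusted p = 0.614). GRP, a neuropeptide gene, was higher (308 ± 154 against 0.234 ± 0.206 CPM, log2 FC 10.33 ± 1.09, adjusted p = 0.00270). Higher too were CLDN5 (171 ± 5.82 against 1.29 ± 1.46 CPM, log2 FC 7.15 ± 0.78, adjusted p = 0.00283) and FOXA2 (152 ± 58.8 against 1.37 ± 1.69 CPM, log2 FC 6.93 ± 0.72, adjusted p = 0.00270). The serotonin receptor gene HTR3A was called as lower at 0.0848 ± 0.0311 against 88.5 ± 39.6 CPM, adjusted p = 0.00102. FUT9 was higher in iAD (60.8 ± 4.04 against 8.20 ± 6.69 CPM, log2 FC 3.03 ± 0.53, adjusted p = 0.0148). ST6GAL1 was lower in iAD (66.2 ± 4.90 against 183 ± 41.0 CPM, log2 FC -1.46 ± 0.31, adjusted p = 0.0292). ST3GAL6 (11.6 ± 2.43 against 40.2 ± 16.6 CPM, log2 FC -1.76 ± 0.31, adjusted p = 0.0144) and B3GAT2 (4.29 ± 0.411 against 88.4 ± 70.6 CPM, log2 FC -4.34 ± 0.71, adjusted p = 0.0118) were lower. Not called were MGAT1 (0.50 ± 0.31, adjusted p = 0.384) and MGAT3 (-1.55 ± 0.45, adjusted p = 0.0768). Nor were MGAT5 (-1.12 ± 0.50, adjusted p = 0.233), FUT8 (-0.28 ± 0.23, adjusted p = 0.527) and ST3GAL4 (0.64 ± 0.25, adjusted p = 0.174). Leaving out iAD KO with DOX, iAD WT with DOX or iE KO without DOX ended the call of DLX2 (5.62 to 5.67). The calls of NEUROG1 (-4.76 to -3.16), NEUROG2 (-5.51 to -3.85), FUT9 (2.71 to 3.37), ST6GAL1 (-1.61 to -1.29), ST3GAL6 (-1.79 to -1.73) and B3GAT2 (-4.44 to -4.26) were lost without iAD KO with DOX or iAD WT with DOX.

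In the cholinergic and peripheral list 0 of 10 genes were higher, 6 lower and 4 not called between iAD and iNN (camera adjusted p = 0.00323, and adjusted p = 0.912 with an estimated correlation). In the pan-neuronal list 0 of 17 genes were higher, 5 lower and 12 not called (0 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.00213, and adjusted p = 0.912 with an estimated correlation). In the GABAergic list 4 of 14 genes were higher, 1 lower and 9 not called (camera adjusted p = 0.0123, and adjusted p = 0.912 with an estimated correlation). The GABAergic median was -2.09 log2 CPM in iNN WT and 1.69 in iNN KO with DOX. Of the 36 lists camera called 9 between iAD and iNN, and fry called 1. Glycosaminoglycan synthesis had 4 of 29 genes higher, 1 lower and 24 not called (camera adjusted p = 0.0123, and adjusted p = 0.912 with an estimated correlation). Branching and bisection had 0 of 8 genes higher, 0 lower and 8 not called (1 higher and 3 lower adjusted over the list alone). In all 1495 genes were called, 787 higher in iAD and 708 lower. With only the 4 libraries of the comparison 82 were called, and 47 of 80 values of named genes lost their call. The count became 377 without iAD WT with DOX, 150 without iAD KO with DOX, 4526 without iNN WT with DOX and 5326 without iNN KO with DOX.

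**Figure D3:**
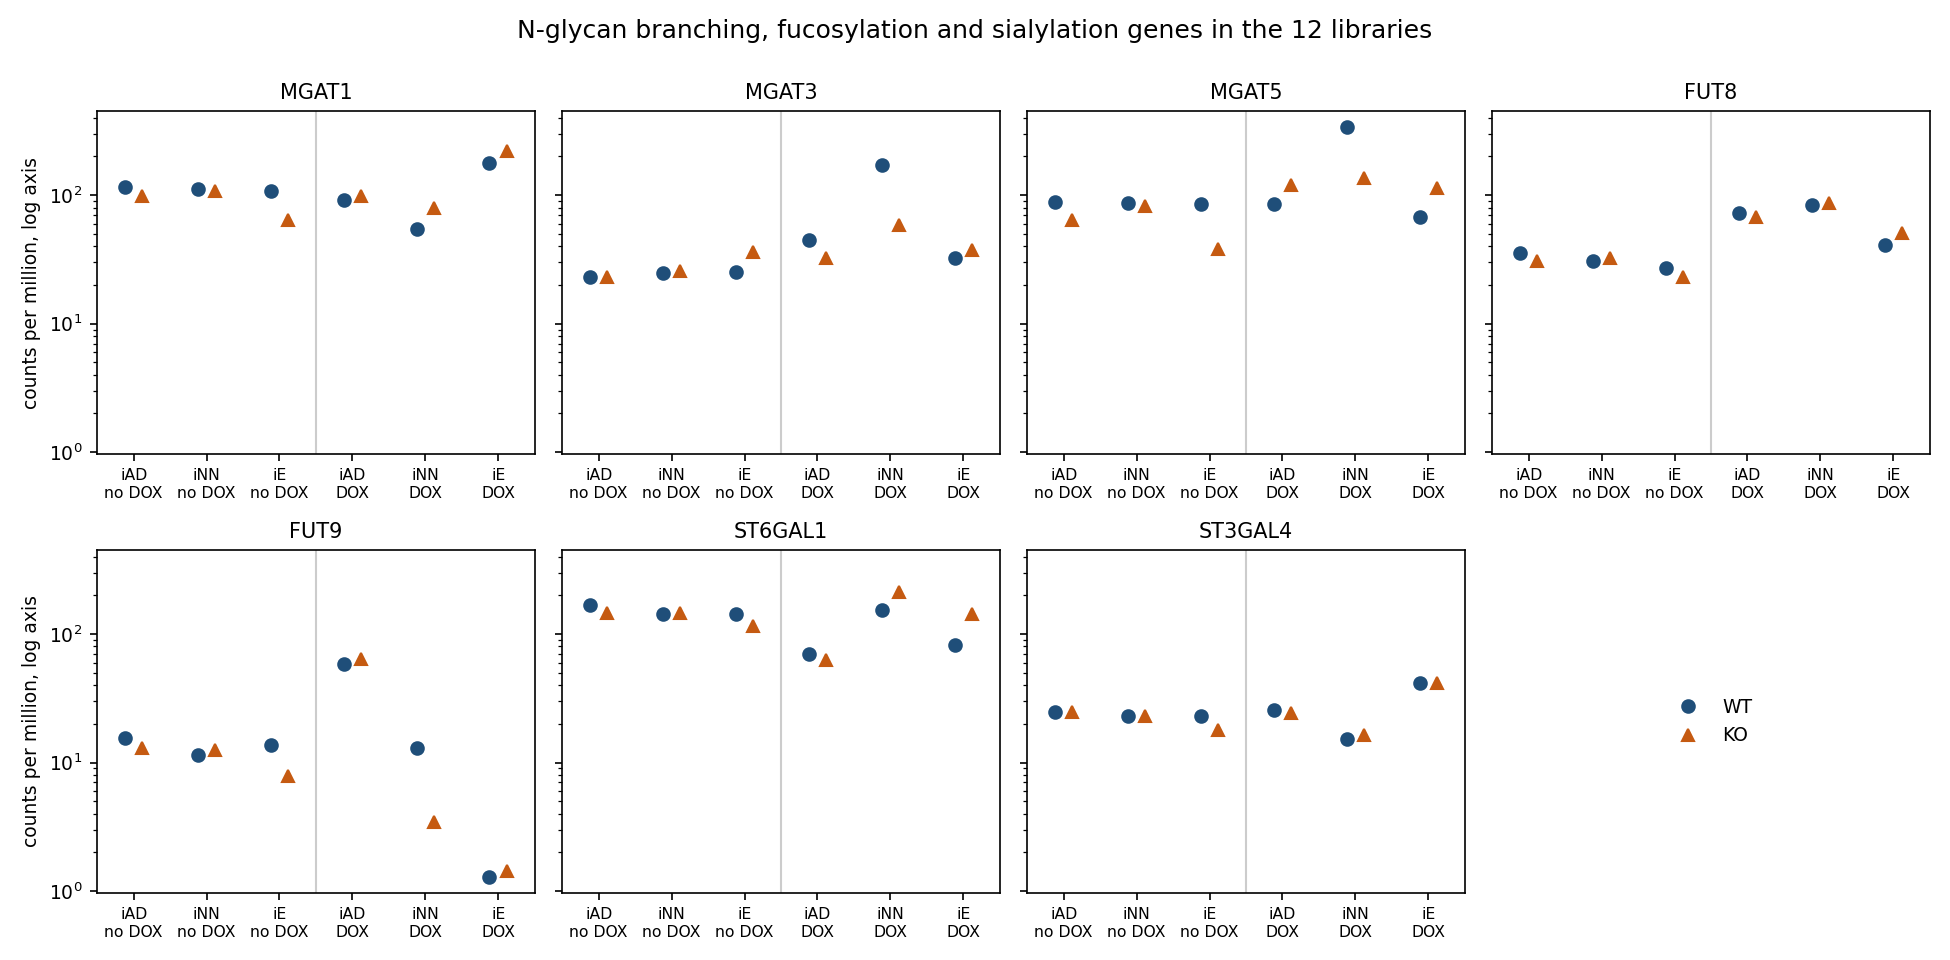
CPM of the 7 N-glycan genes fixed before the data were examined in each of the 12 libraries, on a log scale.

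Whether the DOX response itself differs between lines was asked with interaction contrasts, in which the log2 value is a difference of responses. Against iE, the mean response of iAD and iNN was higher for ELAVL3 (10.20 ± 0.94, adjusted p = 0.00106), DCX (6.96 ± 0.69, adjusted p = 0.00126) and INA (8.83 ± 0.69, adjusted p = 5.95e-04). It was lower for CD93, a receptor of endothelium (-11.75 ± 1.12, adjusted p = 0.00106), for OAS3 of the interferon response (-8.01 ± 1.09, adjusted p = 0.00422) and for TNFRSF10B, a p53 target (-4.86 ± 0.46, adjusted p = 0.00106). Among glycan genes the response was higher for CHST8 (6.37 ± 0.37, adjusted p = 3.16e-04), ST8SIA3 (5.46 ± 0.80, adjusted p = 0.00555) and FUT9 (3.67 ± 0.65, adjusted p = 0.0116). FUT9 rose in iAD, had a negative value that was not called in iNN, and fell in iE. Its mean is thus no response that iAD and iNN share. The mean response was also higher for B3GAT1 of the HNK-1 epitope (2.85 ± 0.40, adjusted p = 0.00463) and the O-glycan sialyltransferase ST6GALNAC5 (2.93 ± 0.42, adjusted p = 0.00517). It was lower for MGAT1 (-1.66 ± 0.38, adjusted p = 0.0306), ST3GAL4 (-1.29 ± 0.31, adjusted p = 0.0360), MAN1A1 (-2.96 ± 0.61, adjusted p = 0.0211) and B4GALT1 (-3.38 ± 0.66, adjusted p = 0.0171). No difference was called for MGAT3 (1.25 ± 0.54, adjusted p = 0.192), MGAT5 (0.30 ± 0.61, adjusted p = 0.814), FUT8 (0.38 ± 0.29, adjusted p = 0.454) and ST6GAL1 (-0.24 ± 0.37, adjusted p = 0.742). The call of ST3GAL4 (-1.50 to -1.12) was lost in any leave-out but that of iNN WT with DOX or iNN KO with DOX. The call of MGAT1 (-1.86 to -1.28) was lost in any leave-out but that of iNN WT with DOX, iNN KO with DOX or iE WT without DOX. Leaving out iAD WT without DOX, iE KO with DOX, iE KO without DOX, iE WT with DOX or iNN WT without DOX ended the call of MAN1A1 (-3.06 to -2.52). The call of B4GALT1 (-3.70 to -2.89) was lost without iAD KO with DOX, iE KO with DOX, iE KO without DOX or iE WT with DOX. Leaving out iE KO with DOX or iE WT with DOX ended the call of FUT9 (3.28 to 3.99).

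This contrast called 1803 genes, 1154 higher and 649 lower. Leaving out 1 library without DOX gave 941 (iAD WT), 956 (iNN WT), 1121 (iE WT), 1022 (iAD KO), 1012 (iNN KO) or 509 (iE KO). With DOX the counts were 4158 without iNN WT, 618 without iE WT, 950 without iAD KO, 7531 without iNN KO and 554 without iE KO. ETV2 was not called (1.60 ± 0.76, adjusted p = 0.236), and neither were DLX2, NEUROG1 and NEUROG2. On simulated counts over 21817 genes edgeR recovered 0%, 1.4% and 50% of differences of 2-fold, 4-fold and 8-fold. DESeq2 recovered 5.5%, 29% and 82.8%. Of the 33 genes called by edgeR and 115 by DESeq2, 3 and 43 were unchanged.

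Between iAD and iNN, the response was higher in iAD for CLDN5 (8.46 ± 1.06, adjusted p = 0.0186), FOXA2 (8.94 ± 1.20, adjusted p = 0.0209) and GPX2, an antioxidant enzyme (8.68 ± 0.72, adjusted p = 0.00727). RASSF6, a regulator of apoptosis, had a higher response too (8.99 ± 0.85, adjusted p = 0.00727). Lower was the response of ST3GAL6 (-2.68 ± 0.43, adjusted p = 0.0355) and HTR3A (-10.03 ± 0.71, adjusted p = 0.00524). None of the 7 fixed N-glycan genes was called, with FUT9 at 2.81 ± 0.71, adjusted p = 0.127 and ST6GAL1 at -1.58 ± 0.43, adjusted p = 0.154. DLX2, NEUROG1, NEUROG2 and ETV2 were not called either. Of the iE libraries only KO without DOX was left out for this contrast. The call of ST3GAL6 (-2.76 to -2.59) was lost in each leave-out that was run but that of iNN WT with DOX or iNN KO with DOX. The call of FOXA2 (8.21 to 9.18) was lost without iAD KO with DOX, iAD KO without DOX, iAD WT with DOX, iAD WT without DOX, iE KO without DOX or iNN WT without DOX. Leaving out iAD KO with DOX, iAD KO without DOX, iAD WT with DOX, iAD WT without DOX or iNN WT without DOX ended the call of CLDN5 (7.64 to 9.38). The calls of GPX2 (8.33 to 8.62) and RASSF6 (8.34 to 9.28) were lost without iAD KO with DOX, iAD KO without DOX or iNN WT without DOX. Leaving out iAD KO with DOX or iNN WT without DOX ended the call of HTR3A (-10.26 to -10.09). The contrast called 167 genes, 112 higher and 55 lower. Without DOX, leaving out iAD WT gave 16, iNN WT 0, iAD KO 1, iNN KO 30 and iE KO 51. With DOX, leaving out iAD WT gave 22, iNN WT 2231, iAD KO 0 and iNN KO 3535.

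The KO was compared with WT over the 6 states, to ask whether it has an effect common to all of them. Embryonic globin genes mark early red cells, and HBE1 had the smallest p at a log2 FC of 4.37 ± 0.48 (adjusted p = 0.411). Its difference was 4.61 in iE with DOX and 0 to 2.56 in the other states. MALAT1, a nuclear RNA, was higher in KO in 6 of 6 states (0.91 ± 0.16, adjusted p = 0.995), as was KCNV1, a potassium channel gene (1.75 ± 0.32, adjusted p = 0.995). SMYD2, a methyltransferase gene, was lower in 6 of 6 (-0.69 ± 0.14, adjusted p = 0.995). FAXDC2, PROX1 and MVP, each at a smaller unadjusted p than SMYD2, were also higher in KO in 6 of 6 states. These genes were picked for their small p, and the error is the disagreement between states. The same direction in 6 of 6 states is thus largely fixed by that choice and is no separate support. MGAT5 stood at -0.29 ± 0.29, adjusted p = 0.995. ST8SIA2 stood at -0.78 ± 0.37, adjusted p = 0.995. Of the lineage factors, DLX2 stood at 0.44 ± 0.82, adjusted p = 0.995. The others were NEUROG1 at -1.34 ± 0.57, adjusted p = 0.995, NEUROG2 at -0.59 ± 0.54, adjusted p = 0.995 and ETV2 at -0.51 ± 0.39, adjusted p = 0.995.

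No gene was called by edgeR between KO and WT, with 750 at unadjusted p under 0.05, and DESeq2 called 6 (5 higher, 1 lower). Without iNN WT with DOX or iNN KO with DOX edgeR called 2. By list, hematopoietic genes gave 0 of 10 genes higher, 0 lower and 10 not called (1 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.00169, and adjusted p = 0.848 with an estimated correlation). Hypoxia and glycolysis genes gave 0 of 12 genes higher, 0 lower and 12 not called (camera adjusted p = 0.00169, and adjusted p = 0.848 with an estimated correlation). Endothelial genes had a median of 0.62 (camera adjusted p = 0.00538, and adjusted p = 0.848 with an estimated correlation). Early mesoderm genes had a median of 1.09 (camera adjusted p = 0.0417, and adjusted p = 0.848 with an estimated correlation). Metallothioneins had a median of 1.12 (camera adjusted p = 0.0273, and adjusted p = 0.848 with an estimated correlation). In iNN with DOX the KO minus WT medians of endothelial, early mesoderm, and hypoxia and glycolysis genes were 3.65, 5.66 and 2.56. In iE without DOX that of the metallothioneins was 5.14, and in iE with DOX that of hematopoietic genes was 1.61. Of the 36 lists camera called 5 for the KO, and fry called 0. Among the N-glycan lists, medians lay at -0.02 for branching and bisection (camera adjusted p = 0.488) and -0.06 for sialyltransferases (camera adjusted p = 0.488). On simulated counts over 21817 genes edgeR recovered 27.4%, 89.4% and 97.2% of changes of 2-fold, 4-fold and 8-fold. DESeq2 recovered 58.1%, 98.5% and 97.2%. Of the 159 genes called by edgeR and 225 by DESeq2, 13 and 54 were unchanged.

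Whether the KO effect differs with DOX was the last question. The hematopoietic factor gene KLF1 had a difference of 4.39 ± 1.79, adjusted p = 0.989. That of the interferon gene OAS2 was 5.69 ± 1.93, adjusted p = 0.989. The cholinergic transporter gene SLC18A3 had -5.67 ± 1.78, adjusted p = 0.989. Among glycan genes MAN1A1 stood at 1.24 ± 0.40, adjusted p = 0.989, B4GALT1 at 1.25 ± 0.48, adjusted p = 0.989 and MGAT5B at -1 ± 0.37, adjusted p = 0.989. edgeR called 0 genes, with 704 at unadjusted p under 0.05, and DESeq2 called 1. Separately, the KO was tested over the 3 states without DOX (0 called by edgeR, 415 at unadjusted p under 0.05) and the 3 with DOX (0 called, 1133 at unadjusted p under 0.05). On simulated counts over 21817 genes edgeR recovered 0%, 15.2% and 58.8% of differences of 2-fold, 4-fold and 8-fold. DESeq2 recovered 4.5%, 57.6% and 95.6%. Of the 55 genes called by edgeR and 157 by DESeq2, 5 and 51 were unchanged.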

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

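The tests of the iNN KO library, of the metallothioneins and of exchanged labels were chosen after the results were seen, and those of the MHC region, the MAPT region and overlapping exons before, though with the counts of some of their genes known.

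Differences between groups met the rule for a closer look, each by an interaction test. The DOX response of iAD and iNN against that of iE differed for 1803 genes, and that of iAD against iNN for 167. Among the fixed N-glycan genes the difference from iE was -1.66 for MGAT1, 3.67 for FUT9 and -1.29 for ST3GAL4 on the log2 scale. The value of FUT9 averages a rise in iAD and a negative value in iNN that was not called. No group has 4 libraries, so no library was tested as far from the others.

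The iNN WT and KO libraries with DOX stood apart from each other, with 774 genes over 8-fold higher in KO and 74 lower among those at a mean log2 CPM of at least 1 in these 2, and which of the 2 is unusual is left open. For the KO library, a library of another cell line is argued against by BPIFB4, a gene of the iNN line, at 790 counts here and 292 in the WT partner, against 0 to 5 in the 8 libraries of the other lines. Undifferentiated cells mixed in would hold 335 genes lost in WT at 1 common share of their level without DOX, but the 90th percentile of the shares was 9.09 times the 10th (median 29.9%), with DNMT3B at 3.81% and LIN28A at 28.8%, which argues against unchanged cells as the only cause. For cells of the iE line with DOX the ratio was 100.3 over 88 genes, which argues against them too. An effect of genotype may be present and cannot be told apart from a difference of 1 culture, since there is 1 iNN KO library with DOX.

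Some list genes had almost no counts in any library. Reads shared with alternate copies of the MHC region could explain part of this, since 96.2% of 156 protein-coding genes there stayed under 10 counts in every library, against 14.6% on the rest of chromosome 6. For the MAPT region the share was 83.3% (5 of 6 genes), against 16.8% on the rest of chromosome 17. Exons that overlap another gene, counted without strand, could explain MGAT2, GALNT4 and NDST2, since the median of these and of TUBB3 and GMPPB was 82.9% of exonic bases inside other genes, against 0% (highest 72.5%) for 443 other list genes. For TUBB3 (35.8%) and GMPPB (54.1%) this is left open, since PRPH had 6591 counts at 56.2% and ECSCR 748 at 72.5%. No biological explanation was tested.

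Metallothioneins were high in the iE KO library without DOX, where the list median lay 5.14 above WT on the log2 scale. Other genes differed too, with 21.7% over 2-fold apart. DDIT3, TRIB3 and CHAC1 of the unfolded protein response list lay 3.72, 3.46 and 2.92 above WT. In iAD without DOX they lay 2.7, 2.46 and 2.12 above WT, and in iNN 0.52, 0.22 and 0.21. HSPA5 of that list was at -2.34 in iE, and the list medians were -0.27 in iE and -0.1 in iAD. For the metallothioneins, a KO effect shared by the 3 lines without DOX is argued against, since the higher of the other 2 differences was 0.58. A culture condition of 1 library, such as metal in the medium, might also be the cause and cannot be told apart, since there is 1 such library. An effect of genotype in iE cells alone stays open in the same way.

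Exchanging the WT and KO labels within states gave 32 splits. The real one called 0 genes for the KO and the highest other 0, so that 32 of 32 called as many was fixed beforehand and decides nothing about chance. The same holds for the KO effect with against without DOX, at 0 genes in the real split and 0 in the highest other (32 of 32). For the KO at unadjusted p under 0.05, the real split had 750 genes and the highest other 1213.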

How the results depend on the processing

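All alternatives were planned except leaving out both iNN KO with DOX and iE KO without DOX and leaving out a library outside a comparison, which were chosen after seeing the data. With DESeq2 size factors all 11 counts of genes stayed within 1.5 times the reported ones, as did the 9 that can be fitted with no genotype term. Without a filter for low counts the response of iAD against iNN gave 598 genes, the lines without DOX 29 and the KO 1, where more genes are tested. With the stricter filter the lines without DOX gave 1. With the 6 libraries without DOX as 1 group, counts were 10549 (iAD), 10303 (iNN), 7689 (iE), 2429 (iAD against iNN, and their responses) and 6623 (response against iE). Among named genes MT1F in iAD turned to -0.031. With only the 4 libraries of a comparison few degrees of freedom are left. There edgeR called more in iAD (11070, against 6519) and for iAD against iE (8328, against 4205). It called fewer in iNN (593), for iNN against iE (0) and for iAD against iNN (82), each of which holds both iNN libraries with DOX. Few degrees of freedom alone thus do not account for the falls. DESeq2 called 3033 for iAD against iNN, 3523 and 1151 for the responses, 52 for the lines without DOX, 6 for the KO and 1 for its change with DOX. It stayed within 1.5 times for the rest (8015 in iAD, 8475 in iNN, 5403 in iE). Without the iNN line the KO gave 6. Without both iNN KO with DOX and iE KO without DOX the counts were 11403 (iAD), 11575 (iNN), 7137 (iE), 10431 (iNN against iE), 9596 (iAD against iE), 6364 (iAD against iNN), 6834 and 4528 (responses), 33 (lines without DOX), 10 (KO) and 0 (KO with DOX). Gene list tests called by camera (68 of 252) fell to 0 with an estimated correlation and were 80 with fry, which called 0 for the KO where camera called 5, and 1 for iAD against iNN where camera called 9. Where no construction is named, the cause was not tested.

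Leaving out 1 library gave 1906 to 10517 genes in iAD, 1956 to 10831 in iNN, 1273 to 7780 in iE, 1594 to 9478 for iNN against iE, 1169 to 8507 for iAD against iE and 150 to 5326 for iAD against iNN. The responses gave 509 to 7531 against iE and 0 to 3535 for iAD against iNN, the lines without DOX 0 to 38, the KO 0 to 2, and the KO with DOX 0 to 0. Where a state keeps 1 library, that lone library is assumed to vary like the other groups, and fewer libraries are part of the lower counts. Over 6943 values of named genes, 5572 stayed on their side of the threshold, 1222 lost a call, 144 gained 1 and 5 turned. The 5 turned without iNN KO with DOX, and their other end was reached without iNN WT with DOX. With DOX in iNN, GAD1 lay at -0.83 to 6.11, OLIG2 at -0.36 to 6.30 and LUM at -3.90 to 10.32. OSTC lay at -1.55 to 1.07 in iAD against iNN, and RGS5 at -4.86 to 1.95 between the responses of iAD and iNN. Without both iNN KO with DOX and iE KO without DOX these were -0.74, -0.19, -3.91, 1.04 and 1.90. DESeq2 kept 893 of 947 named values on their side, DESeq2 size factors 936 of 947, no filter 894 of 947, and only the 4 libraries 374 of 608.

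In simulated counts edgeR recovered 0% of 2-fold changes in iNN with DOX and 72.1% of 8-fold ones, so the absence of a call does not exclude a 2-fold change. Unchanged genes made up 57 of 160 DESeq2 calls there and 6 of 68 edgeR calls, so the extra calls of DESeq2 are less certain.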

Other observations

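No test of a hypothesis is reported in this part, so none was chosen after a result was seen, and the genes below were chosen after their values were seen.

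Some genes of red cells differed between the 2 iE libraries with DOX. The KO minus WT difference on the log2 scale was 4.61 for HBE1, 4.72 for HBZ and 5.60 for the carbonic anhydrase gene CA1. GATA1, a factor of red cells and platelets, differed by 3.59. The hematopoietic list had a median of 3.99 log2 CPM in KO and 1.41 in WT.

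Developmental genes of other lineages were present in the iNN KO library with DOX. LUM, a collagen-binding gene, stood at 73.0 CPM against 0 in WT, and HAND1, a mesoderm factor, at 46.4 CPM against 0. The early mesoderm list had a median of 3.85 log2 CPM in KO and -1.47 in WT, and the hypoxia and glycolysis list 7.77 and 5.25. IGFBP2, a growth factor binding gene, stood at 424% of its level without DOX. This was 1270 CPM, against 11.3 in the WT partner. The means of the other lines with DOX were high too, at 854 CPM in iAD and 954 in iE.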
